A study of Homo sapiens with 3 samples.

How the data were processed

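Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on wild-type KBM7 cells, a near-haploid human line from a chronic myeloid leukaemia that carries the BCR-ABL fusion. The series holds 3 libraries. H3K27ac, an acetylation found at active promoters and enhancers, was pulled down with the Abcam antibody ab4729. H3K4me3, a methylation found mainly at promoters, was pulled down with the Millipore antibody 07-473. The remaining library is the input, DNA that was not immunoprecipitated. Per the labels' protocols, the cells grew in IMDM with 10% serum, chromatin was sheared with a probe sonicator on ice, and libraries were made with the Rubicon ThruPLEX kit. Each mark has 1 library, so there are no replicates, no spread between samples could be measured and no comparison between conditions was possible.

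Per the submitters' processing notes, Bowtie2 2.3.4 and bedtools 2.20.1 were used and the genome build was hg38. The peak caller and the tool that ranked the super-enhancers are not given in the sources used here. The deposited values come as 1 peak list per mark and 1 table of super-enhancers, which are long regions made by joining neighbouring H3K27ac peaks. Each peak list rests on a single immunoprecipitated library, so no libraries of a mark were pooled. Whether the input also entered the peak calling was not established.

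In each peak list the authors give a fold enrichment at the summit, the −log10 of a p-value, the −log10 of a q-value and the summit position. The score column of the deposited lists equals 10 times the −log10 q, rounded down, in 100% of the rows of both lists. The lowest −log10 q is 1.32 for H3K27ac and 1.33 for H3K4me3, which places the cut-off of the deposited lists at a q of 0.05. The deposited fold and −log10 p together fit, in 100% of the rows, a whole-number pileup of fragments at the summit and an expected background. The fold is (pileup + 1)/(expected + 1) and the p is the upper Poisson tail, within a tolerance of 0.01 on the −log10 scale. This gave the number of fragments behind each peak. The fold of a peak is the authors' value and was used only to describe and rank peaks within 1 list.

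The super-enhancer table gives, per the file headers, a total H3K27ac signal and a total input signal over each region, their difference, a rank by that difference and a target gene. The scaling of the signal is not given in the sources used here, so totals and differences were compared only between regions of this table, beside the ratio to input and the density per base. Per the name of the deposited table, the target is a nearby gene in the same topologically associating domain, chosen on its expression in TT-seq, a measurement of newly made RNA. The targets were therefore selected by the authors on expression and are not independent evidence that a gene is expressed. Here the input library was used directly only through its column in this table, and the table holds only the regions that the authors called super-enhancers.

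Gene positions came from the RefSeq gene table of GRCh38.p14, the same build as the files. It gives the start and end of each gene but no strand, and no reference genome was used here. Promoters were therefore approximated by both ends of each gene record, with a window of 1 kb either side, for 19974 protein-coding genes on chromosomes 1 to 22 and X. The tests had been planned for transcription start sites. A peak at a gene end may thus lie at the 3′ end, and a promoter inside a gene is missed. Among 10991 genes of at least 20 kb, 70.0% had H3K4me3 at 1 end and 4.28% at both. Of the 462 target genes, 450 matched the table by symbol, 11 by transcript accession and 1 by an older symbol.

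Peaks on chromosomes 1 to 22 and X entered the comparisons. Peaks overlapped when they shared at least 1 bp, and the share was set against 100 random circular shifts of the intervals within each chromosome. Super-enhancers were set against 100 random placements of regions of the same lengths that had to touch an H3K27ac peak. Shares have 95% Wilson intervals and ratios of rates have exact conditional intervals. Ratios of medians and of percentiles have intervals from 200 bootstrap resamples of peaks. All of these cover counting or resampling error only, since fragments, peaks and genes are not replicates. Gene lists were tested with two-sided Fisher's exact tests and Benjamini-Hochberg adjustment over 14 lists, at an adjusted p of 0.05. These tests describe the lists in these libraries. The background for promoters was all protein-coding genes. For super-enhancer targets it was the 12648 protein-coding genes that had an H3K27ac peak at an end or were targets, a stand-in for the genes that could have been chosen. The odds ratio of a list is computed with 0.5 added to each cell of its table.

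The 14 lists hold 332 genes, of which 5 are in more than 1 list. They and the rule for named genes were fixed before the data were examined. The rule takes the targets of the 10 longest and the 10 top-ranked super-enhancers and up to 6 targets per list. It adds the 10 genes with the widest H3K4me3 interval at an end, the genes at the 5 strongest peaks of each mark, and up to 4 members without both marks from each list past the threshold. Other genes are named as members or counts of those lists and were chosen after their values were seen. Some genes that the rule takes are not reported here. H3K4me3 width at target genes was given as a percentile among 10000 random gene lists of the same size, matched on the deciles of the authors' fold.

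Alternatives were a q of 1e-05 or less, the top 50% of peaks by fold, windows of 500 bp and 2.5 kb, other measures of overlap, other backgrounds and the longer regions only. Added after the data were seen were the whole gene body in place of its ends, H3K4me3 peaks away from gene ends, tests of the lists for 1 mark without the other, and leaving out segments with raised expected background. Such a segment is a run of at least 3 bins of 1 Mb, each with at least 5 H3K27ac peaks and a median expected background of at least 1.5 times the median bin. Bins with fewer peaks were left out first, so a segment can span bins that were not measured. On simulated data the fragment numbers were recovered in 100% of peaks, and a planted gene list passed in 99 of 100 runs. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.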

Results

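Wild-type KBM7 cells, a near-haploid human myeloid leukaemia line, were profiled for H3K27ac and H3K4me3 with 1 library each, beside 1 input library. The series belongs to a study of how far the transcription of genes that specify a cell type depends on Mediator, the complex that links enhancer-bound factors to RNA polymerase II. These libraries describe the promoters and super-enhancers of the untreated cells. The H3K27ac list holds 96659 peaks on chromosomes 1 to 22 and X with a median of 21 fragments at the summit (interquartile range 16 to 42, highest 307). The H3K4me3 list holds 36951 peaks with a median of 39 fragments (18 to 221, highest 345). The median peak was 417 bp wide for H3K27ac and 793 bp for H3K4me3, and the peaks covered 83.7 and 49.5 Mb. The total number of reads per library is not given in the sources used here. With 1 library per mark no value has a replicate error, and intervals cover counting or resampling error only.

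In the full lists H3K4me3 peaks lay mostly where H3K27ac was also present, whereas most H3K27ac peaks, in a longer list with many weak peaks, carried no H3K4me3. At HOXA7, HOXA9 and HOXA10, homeobox genes of early myeloid cells, a single H3K4me3 interval of 20254 bp met an H3K27ac interval of 20708 bp. At CDKN1B, which encodes the cell cycle inhibitor p27, the intervals were 15244 and 16383 bp wide and were shared with the neighbouring APOLD1 and GPR19. Among H3K4me3 peaks 30979 of 36951 (83.8%, 95% interval 83.5 to 84.2) overlapped an H3K27ac peak, 14.2 times the mean of shifted intervals (5.89%, highest 6.93%). Among H3K27ac peaks 34834 of 96659 (36.0%, 35.7 to 36.3) overlapped H3K4me3, 12.5 times the shifted mean of 2.88% (highest 3.40%). H3K27ac peaks that overlapped were wider (median 1125 against 311 bp) and had a higher fold enrichment (11.5 against 3.91) than those alone. In the lowest quartile of H3K27ac peaks by fold 11.0% overlapped H3K4me3, and in the highest 89.5%. The share of H3K27ac peaks was 71.8% when that list was reduced to its 36951 strongest peaks, the number in the H3K4me3 list, which changes its length and its strength together. The share of H3K4me3 peaks was then 73.1%, without the contrast between the marks.

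The strongest peaks of both marks lay at gene ends more often than weaker ones. In the highest quartile by fold 85.7% of H3K4me3 peaks and 50.7% of H3K27ac peaks did. For H3K4me3 the 5 peaks of highest fold were at PTBP1, a splicing regulator (chromosome 19, 797306 to 801910, fold 109), NF1, a negative regulator of RAS (fold 108), KMT2B, an H3K4 methyltransferase (fold 105), TESK1 (fold 105) and NOL9 (fold 104). Their summits held 304 to 319 fragments, fewer than the highest in the list (345). The expected background was 1.92 at PTBP1, NF1, TESK1 and NOL9, the lowest of the list (median 2.66), and 1.97 at KMT2B. For H3K27ac the peaks of highest fold included ATXN2L (chromosome 16, 28821634 to 28825290, fold 63.9), SLBP, the histone mRNA binding protein (60.3), SMG9, a factor of nonsense-mediated decay (60.0), and a site 19103 bp from TEX44 (62.6). The background was 2.80 at SLBP and SMG9, the lowest of that list (median 3.63), 3.04 at ATXN2L and 3.20 at the TEX44 site. Peaks within 1 kb of a gene end made up 18.9% of the H3K27ac list (18231 peaks, 18.6 to 19.1) and 36.3% of the H3K4me3 list (13399 peaks, 35.8 to 36.8). The median fold of H3K27ac was 15.3 at gene ends and 4.20 elsewhere, a ratio of 3.64 (bootstrap interval 3.57 to 3.72). For H3K4me3 it was 57.9 and 6.06. Gene ends stood in for transcription start sites, and counting the whole gene body raised the shares to 67.6% and 73.8%.

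Most protein-coding genes carried both marks or neither. Of 19974 genes, 12062 (60.4%) had H3K27ac and H3K4me3 at an end, 6077 (30.4%) had neither, 1268 (6.35%) had H3K4me3 only and 567 (2.84%) had H3K27ac only. The odds ratio of the marks across genes was 102. MYC, GATA2 and MED12 were among the genes with both, and GATA1 and HBB among those with neither.

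**Figure D1:**
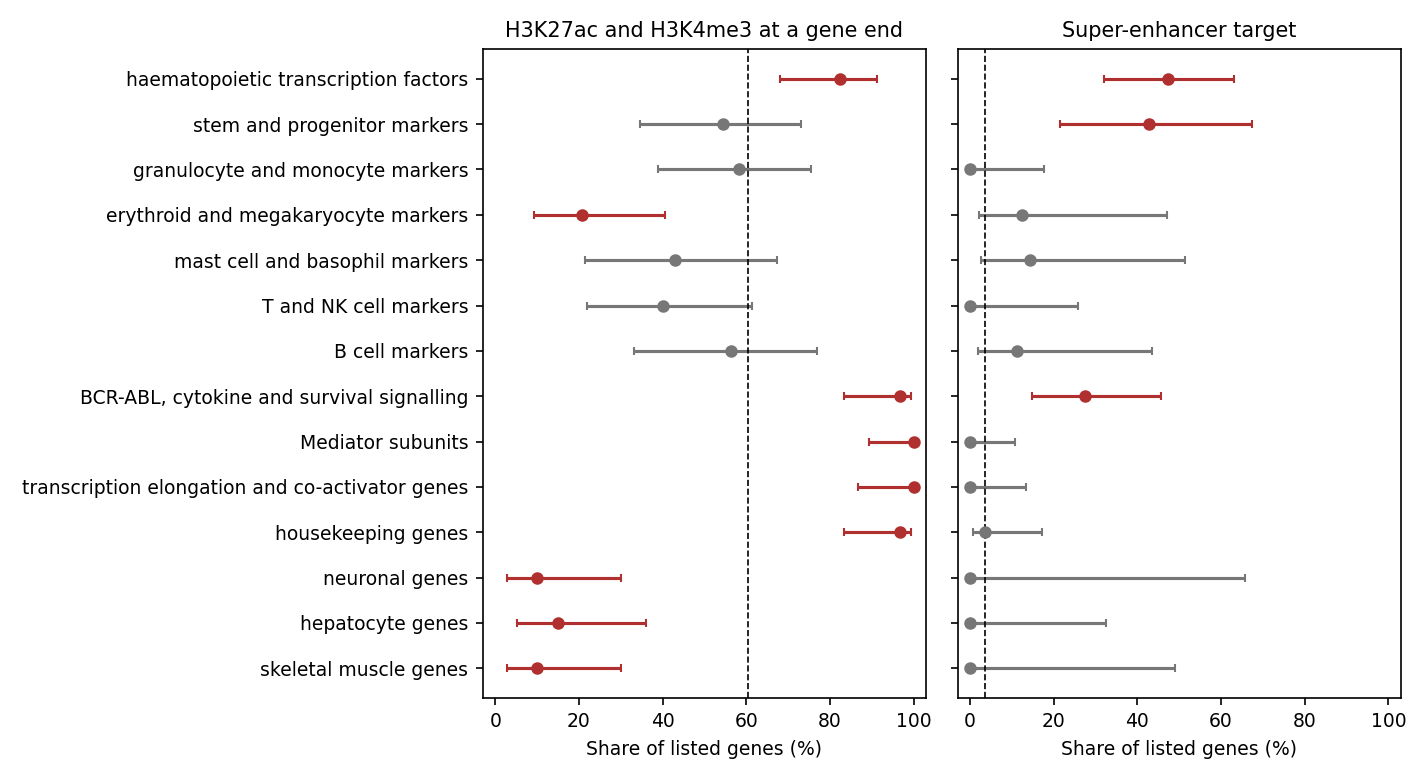
Share of the genes of each list with both marks at a gene end (left) or chosen as a super-enhancer target (right), as points with 95% Wilson intervals, dashed lines giving the mean share among genes outside a list and red marking lists past an adjusted p of 0.05. All 32 Mediator subunit genes carried both marks and none was a super-enhancer target, a list too short to show a shortage against 3.65% of other genes. Of 36 haematopoietic transcription factors 17 were targets.

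Genes of the transcription machinery, of BCR-ABL signalling and of general upkeep nearly all carried both marks. All 32 Mediator subunit genes did, among them MED12 (H3K27ac fold 30.0, H3K4me3 fold 62.9), MED1 (17.5 and 58.9) and CDK8 (22.3 and 79.2), the kinase of the complex. So did all 25 elongation and co-activator genes, such as CDK9 (52.2 and 92.5), the kinase of P-TEFb. Of the BCR-ABL, cytokine and survival signalling genes 29 of 30 had both, with BCR at folds of 28.7 and 86.5 and JAK2 at 15.4 and 57.2, and CCND1 had H3K4me3 only (fold 32.1). Of the housekeeping genes 29 of 30 had both, as at ACTB (30.4 and 73.4), and the exception was UBB, a polyubiquitin gene with close copies in the genome. Against 60.3% of other genes, these 4 lists were higher by Fisher's exact test, with adjusted p of 1.74e-06 for Mediator, 1.48e-05 for elongation and 1.54e-05 for each of the other 2.

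Haematopoietic transcription factors carried both marks more often than other genes. The joint list of red cell and platelet genes, not tested apart, and the lists of unrelated tissues carried both marks together less often. Both marks were present at 33 of 40 haematopoietic factors (82.5%, 68.0 to 91.3, Fisher's exact test, adjusted p = 0.00527). GATA2, a stem and progenitor factor, had folds of 30.2 and 81.7 over intervals of 12996 and 11258 bp, and MYB had 39.3 and 57.5. Without both at an end were GATA1 and KLF1, factors of red cell development, IRF8, ETS1, RUNX2, MEF2C and ERG. Of these, ERG had H3K4me3 (fold 45.1) and KLF1 had H3K27ac (fold 5.53) at an end. Inside the gene, however, MEF2C had 18 H3K4me3 peaks (strongest fold 58.1) and 50 H3K27ac peaks. GATA1 also had both marks inside the gene, with folds of 6.32 for H3K27ac and 6.16 for H3K4me3. Only 5 of 24 erythroid and megakaryocyte markers had both (20.8%, 9.24 to 40.5, Fisher's exact test, adjusted p = 0.00017), namely EPOR, TFRC, ITGA2B, GP1BA and GP9. The globin gene HBB had neither, ALAS2 (fold 4.74) and EPB42 (7.35) had H3K27ac only, and ANK1 had H3K4me3 only (46.1). HBA1 and HBA2, nearly identical alpha-globin genes, are uncertain because reads can be shared between them.

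Of the 20 neuronal genes 2 carried both marks, SYP and NEUROG2, and CAMK2A, DCX and ELAVL4 were among those that carried neither. Of the 20 skeletal muscle genes 2 did, TNNC2 and ACTN2, while ACTA1, CASQ1 and DES carried neither and CKM had H3K4me3 only. Of the 20 hepatocyte genes 3 did, APOA1, TF and TAT, while AHSG, ALB and APOB carried neither and APOA2 had H3K27ac only. These counts were below the rest of the genome by Fisher's exact test, with adjusted p of 1.48e-05 for neurons and muscle and 8.10e-05 for liver. By H3K4me3 alone neuronal genes did not pass (10 of 20, Fisher's exact test, adjusted p = 0.212), nor did hepatocyte genes by H3K27ac alone (8 of 20, 0.058). The other blood lists did not pass the test. Both marks were present at 12 of 22 stem and progenitor markers (54.5%, Fisher's exact test, adjusted p = 0.775), such as CD34 and KIT, and at 14 of 24 granulocyte and monocyte markers (58.3%, 0.837), such as MPO and LYZ. They were present at 6 of 14 mast cell and basophil markers (42.9%, 0.348), 8 of 20 T and NK cell markers (40%, 0.0976) and 9 of 16 B cell markers (56.2%, 0.837). T and NK cell markers passed as lower with the top 50% of peaks (Fisher's exact test, adjusted p = 0.00141) and with a window of 500 bp (adjusted p = 0.0156).

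The super-enhancer ranked highest was assigned to MYC, a growth-promoting transcription factor, and lay far from it. It spans 158 kb of chromosome 8 (hg38, 129533854 to 129691821), 1791 kb from the gene, with 146 kb of it inside the long non-coding RNA gene CCDC26. It lies on a segment of raised background, and its rank was 4 when differences on such segments were divided by the background ratio and 158 by the ratio of signal to input. Its H3K27ac signal was 9.79 times its input signal, and it held 46 H3K27ac and 16 H3K4me3 peaks. The next were assigned to SATB1, a chromatin organiser of blood cells (275 kb, chromosome 3, 17891451 to 18166677, 179 kb from the gene), and SLC39A10, a zinc transporter (271 kb, 29.9 kb from the gene). The one assigned to ETV6, a haematopoietic repressor, covered 239 kb of that gene (chromosome 12, 11656262 to 11896930). Ranks 5 to 10 went to LIPC, RHEX, VSIG4, GSE1, MYB and LY86, with signal ratios of 7.45 to 13.5. RHEX, a regulator of erythroid cell expansion, had the widest H3K27ac interval of the list (34095 bp). The region assigned to VSIG4 also contains MIR223, a microRNA gene of granulocytes. Among the 10 longest were also those of GAB2, an adaptor protein in BCR-ABL signalling (203 kb), SPN, which encodes CD43 (152 kb), MYH9 (147 kb) and GNAQ (142 kb).

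**Figure D2:**
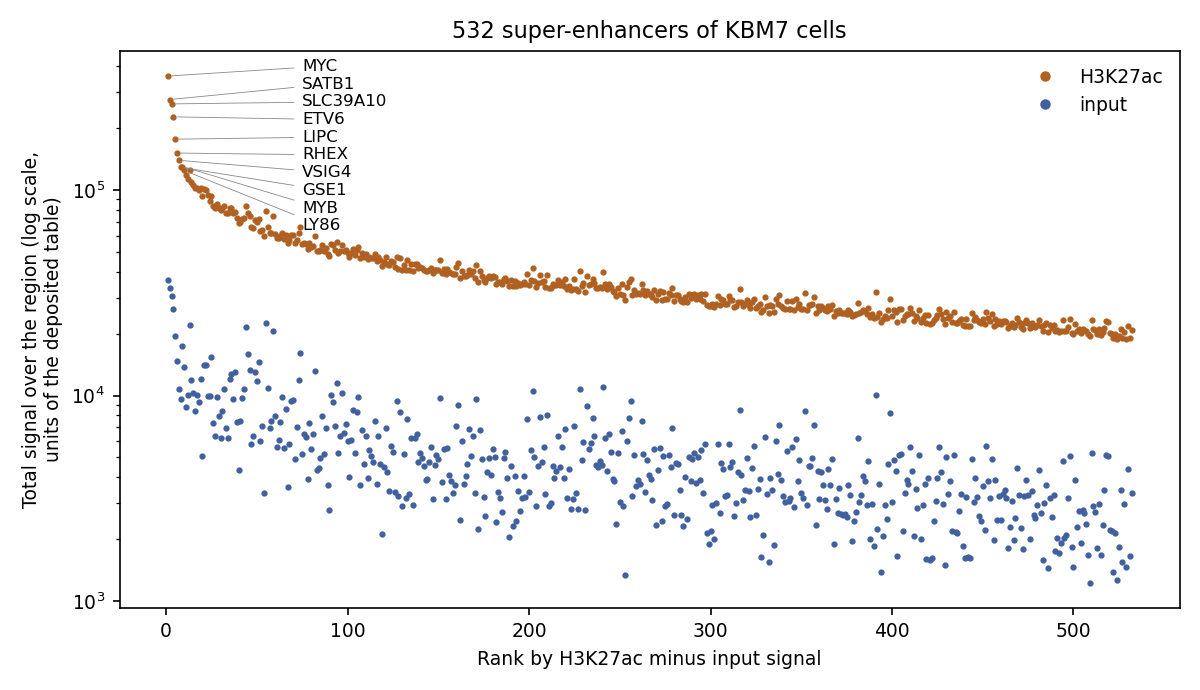
Total H3K27ac signal (orange) and input signal (blue) of each super-enhancer on a log scale, in the units of the deposited table, against its rank by their difference, with the 10 top target genes named. H3K27ac exceeded input in every region, by 3.18 to 21.9 times.

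**Figure D3:**
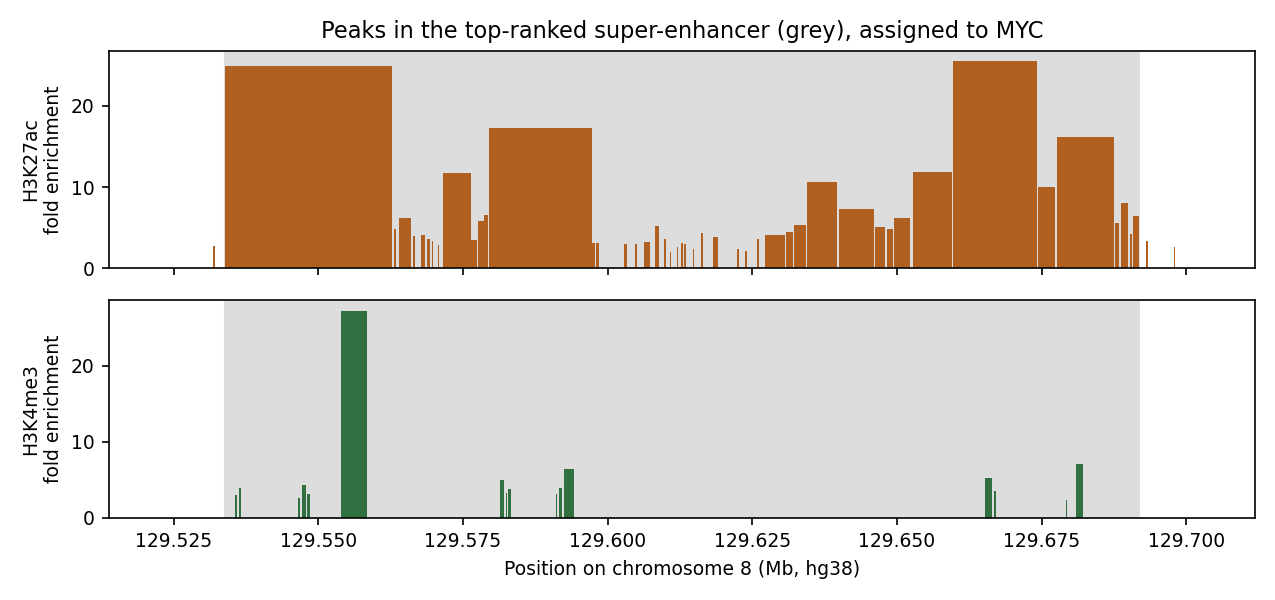
Fold enrichment of each H3K27ac (top) and H3K4me3 (bottom) peak, drawn over its width, along hg38 chromosome 8 around the top-ranked super-enhancer (grey, 129533854 to 129691821). It held 46 H3K27ac peaks and 16 H3K4me3 peaks.

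Together the super-enhancers covered 25.6 Mb with a median length of 41.6 kb (10.4 to 275). The median ratio of H3K27ac to input signal was 8.11 (interquartile range 6.39 to 10.3) and was highest at PTPN7, which encodes a phosphatase of blood cells (21.9), and at SPI1, which encodes the myeloid factor PU.1 (20.2). A target was given for 513 regions, which named 462 genes. Of 510 regions with a measured distance 337 (66.1%) overlapped their target gene and 62 (12.2%) lay more than 100 kb from it. JARID2, SAMSN1 and TOMM20 had 4 super-enhancers each, and CSMD3, GSE1, MSN, RREB1 and RUNX1 had 3.

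Every super-enhancer held a peak of the full H3K4me3 list, and 455 held one of its top 50% by fold, although the mark covered little of most of them. In the regions of SATB1 and SLC39A10 H3K4me3 covered 1.57% and 4.64% of the length, at SPI1 21.2%, and at TAL1, a master factor of blood formation, 37.8%. This share of 100% (99.3 to 100) compared with a mean of 460 regions (441 to 475) in random placements of as many. Those placements only had to touch an H3K27ac peak, whereas super-enhancers overlapped a median of 19. Placements were thus not matched on H3K27ac density, and the excess cannot be told apart from that difference. A peak away from the ends of protein-coding genes was held by 524 super-enhancers. Promoters of non-coding genes and promoters inside genes count as away here. The median covered share was 14.7% (8.67 to 22.5) for H3K4me3 and 60.5% for H3K27ac. Super-enhancers took 12291 H3K27ac peaks, 12.7% of the list (12.5 to 12.9) and 18.1% of its bases. Their peaks had a median fold of 4.74 against 4.47 outside, and 19.8% of them overlapped H3K4me3 against 38.4% outside.

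Haematopoietic transcription factors were strongly represented among super-enhancer targets. Of the 36 that could have been chosen 17 were targets (47.2%, 32.0 to 63.0, against 3.51% of other genes, odds ratio 24.6, Fisher's exact test, adjusted p = 1.62e-14). They were ETV6, MYC, MYB, LMO2, RUNX1, IKZF2, TAL1, FLI1, ERG, SPI1, GFI1, IKZF1, MEF2C, ZEB2, NFE2, BCL11A and ELF1. Those of LMO2 (99.5 kb), a partner of TAL1, and RUNX1 (65.9 kb) were the next longest after MYB (147 kb). Stem and progenitor markers were targets in 6 of 14 cases (odds ratio 20.5, Fisher's exact test, adjusted p = 2.94e-05), namely CD34 (118 kb), ADGRG1 (91.3 kb), CD44 (81.8 kb), ANGPT1, BAALC and SOX4. BCR-ABL, cytokine and survival signalling genes were targets in 8 of 29 (odds ratio 10.6, Fisher's exact test, adjusted p = 2.94e-05), among them GAB2 (203 kb), the survival genes BCL2 (90.8 kb) and BCL2L1 (57.0 kb), PIK3CD (49.7 kb), the kinase PIM1 (43.3 kb) and GRB2 (40.2 kb).

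None of the 32 Mediator genes, the 25 elongation and co-activator genes, the 18 granulocyte and monocyte markers or the 11 T and NK cell markers was a target, and none of these lists passed the test. Among genes outside the Mediator list 3.65% were targets, so lists this short could not have shown a shortage. The housekeeping and the erythroid lists had 1 target, the transferrin receptor gene TFRC, which is in both (1 of 29 and 1 of 8). The mast cell list had TPSAB1 (1 of 7), a tryptase gene with the close copy TPSB2, and the B cell list had PAX5 (1 of 9). None of the 2 neuronal, 8 hepatocyte or 4 muscle genes was a target, and these lists could not have shown a shortage either. The authors chose targets on expression, so membership is not independent of expression. MYC, ANGPT1, BAALC and LYN lie on segments with raised background, and without those segments the same 3 lists passed.

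Genes with a super-enhancer had broader H3K4me3 at their ends than other genes with the mark. IKZF2, an Ikaros family factor of blood cells, had an H3K4me3 interval of 12027 bp, MYB of 10780 bp, GFI1 of 10672 bp and BCL11A of 10171 bp. The widest intervals of all were at genes not assigned a super-enhancer, namely the HOXA genes (20254 bp) and CDKN1B with its neighbours (15244 bp), and ZMYND8 (12153 bp) and MGME1 (11629 bp) were also among the 10 widest genes. The median over 424 targets was 3426 bp (interquartile range 2569.5 to 4650), against 2563.5 bp for 12906 other genes. Random lists matched on fold had a median of 2642.5 bp (95% of them 2522 to 2770.5), and the targets stood at percentile 100 of 10000 such lists. Matching may not have equalised strength, because H3K4me3 summits levelled off, and without it the random median was 2588.5 bp. Nor were the lists matched on expression, on which the authors chose the targets. H3K4me3 was present at an end of 92.2% of 460 protein-coding targets and of 66.1% of other genes. The other genes include those with neither mark, 30.4% of all genes. The higher share in targets does not hold against genes with H3K27ac at an end, of which 12062 had H3K4me3 and 567 did not.

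Along the genome the expected background at H3K27ac peaks was even except on chromosomes 8 and 15. It was 1.95 times the median bin from 8 to 142 Mb of chromosome 8, which holds MYC, LYN and ANGPT1, and 1.81 times from 62 to 89 Mb of chromosome 15. These values rest on 94 and 24 bins, and bins with too few peaks in between were not measured. The input signal per base of the 50 super-enhancers on these segments was 0.194 against 0.0976 for the other 482, a ratio of 1.98. The expected background may itself come from the input, in which case these are not separate measures. The 482 include 4 on chromosome 8 beyond the ends of the segment, whose input was also raised (0.164 to 0.223, against at most 0.148 in the remaining 478). KBM7 cells are known to be disomic for chromosome 8. The segments held 18 of the 100 top-ranked super-enhancers, and their median ratio of H3K27ac to input was 4.92 against 8.36 elsewhere. The segment rule was set after the profile was seen.

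**Figure D4:**
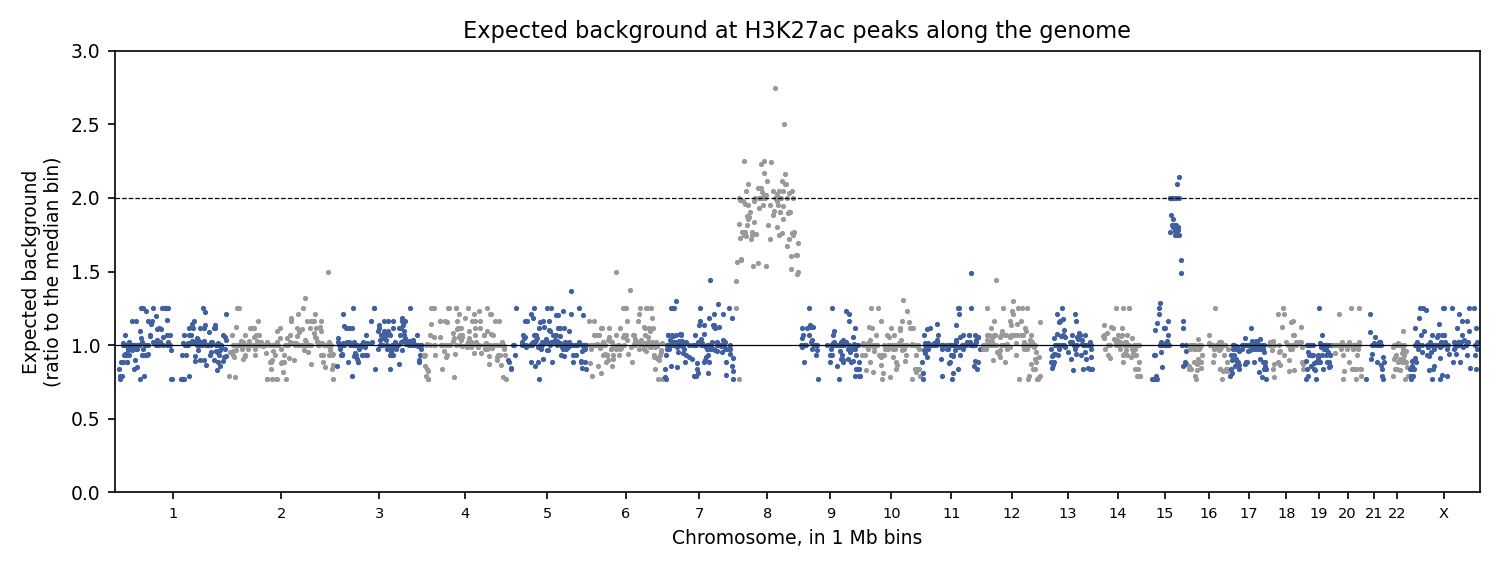
Median expected background at H3K27ac peaks per 1 Mb bin, as a ratio to the median bin, along chromosomes 1 to 22 and X, with solid and dashed lines at ratios of 1 and 2. Bins of chromosome 8 and of the distal part of chromosome 15 lie near 2 and nearly all others near 1.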

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

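All overlap settings here were chosen before the data were examined. Peaks on sequences outside chromosomes 1 to 22 and X entered no comparison. The H3K27ac list holds 38 such peaks on 12 unplaced or unlocalised sequences, with a highest fold of 17.4. The H3K4me3 list holds 45 on 16 sequences, with a highest fold of 49.3. They drew attention because they are signal outside the main measurement. Including them left the overlap of H3K27ac peaks at 36.1% and of H3K4me3 peaks at 83.8%.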

How the results depend on the processing

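Settings on gene bodies, on peaks away from gene ends and on the raised segments were chosen after the data were seen. No paired analysis was possible because each mark has 1 library. Of 62 alternative values of the main results 33 stayed within 1.5 times a count, on the same side of a test or within the interval of a share, and 29 moved beyond it. With the H3K27ac list reduced, most of its peaks overlapped H3K4me3, unlike in the full list. The causes were not tested, apart from changes that follow from how a setting is built. The planned use of 1 start site per gene was not run, since the gene table has 1 record per gene and no strand. Leaving intervals unmerged changed nothing because none overlap within a list. What depth limits was not tested, and the median H3K27ac summit rests on 21 fragments.

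The share of H3K27ac peaks overlapping H3K4me3 (36.0%) was 45.5% at a q of 1e-05 or less, 40.7% in the top 50% by fold, 27.4% with at least 50% of the peak covered, 33.2% by summits and 71.8% with the H3K27ac list reduced to its strongest peaks, as many as in the H3K4me3 list. The share of H3K4me3 peaks overlapping H3K27ac (83.8%) was 83.2%, 86.9%, 78.3%, 81.7% and 73.1% in the same order. The share of H3K27ac peaks at gene ends (18.9%) was 24.7% at the stricter q, 30.5% in the top 50%, 16.4% with 500 bp, 26.9% with 2.5 kb and 67.6% over gene bodies. For H3K4me3 (36.3%) it was 40.4%, 64.1%, 34.3%, 42.9% and 73.8%. The ratio of median fold at gene ends over elsewhere for H3K27ac (3.64) was 3.34 at the stricter q, 2.92 in the top 50%, 4.13 with 500 bp and 2.03 with 2.5 kb, above 1 each time. The share of H3K27ac peaks inside super-enhancers (12.7%) was 13.8% at the stricter q, 13.9% in the top 50%, 18.1% by bases and 12.3% without the raised segments. That every super-enhancer held H3K4me3 did not hold for stronger peaks, with 529 regions at the stricter q and 455 in the top 50%. The longer regions alone gave 266, which is all of that smaller list.

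Genes with both marks ranged from 11562 to 12611, and median H3K4me3 width at targets from 3426 to 4092.5 bp against 2588.5 to 2888.5 bp in random lists, at percentile 100, which cannot rise further. In each of the 7 alternatives 3 lists passed among super-enhancer targets. Of 196 values for single lists 192 kept their side of the test. The 2 that no longer passed were neuronal genes by H3K4me3 alone (odds ratio 0.498, Fisher's exact test, adjusted p = 0.212) and hepatocyte genes by H3K27ac alone (0.395, 0.058). The 2 that newly passed were T and NK cell markers in the top 50% (0.198, 0.00141) and with 500 bp (0.311, 0.0156).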

Other observations

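The tests of gene lists for 1 mark without the other, the nearest peaks, the segment rule and the value expected of the divided ranking without an effect of copy number were chosen after the data were seen. Neuronal genes, few of which carried both marks, often carried H3K4me3 without H3K27ac. This held for 8 of 20, against 6.31% of other genes (40%, 21.9 to 61.3, odds ratio 10.1, Fisher's exact test, adjusted p = 0.000229 over 14 lists). The 8 were STMN2, MAP2, NEFL, NEFM, GRIN1, SLC17A7, SLC32A1 and NEUROD1, with folds such as 36.9 at GRIN1, a glutamate receptor subunit, 24.9 at MAP2 and 3.76 at NEFL. No hepatocyte gene had this state. Hepatocyte genes instead had H3K27ac without H3K4me3 in 5 of 20 cases (25%, odds ratio 12.2, Fisher's exact test, adjusted p = 0.00276), namely APOA2, APOC3, SERPINA1, CYP2E1 and F2, with low folds such as 3.57 at APOA2 and 4.74 at SERPINA1. Granulocyte and monocyte markers did so in 4 of 24 (16.7%, odds ratio 7.55, Fisher's exact test, adjusted p = 0.0304). These were the granule genes PRTN3 (fold 5.26) and AZU1 (6.05) and the receptor genes CSF1R (6.84) and CSF3R (25.3).

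A super-enhancer of 40.2 kb on chromosome 4 (hg38, 116319293 to 116359516) differed from most others and was chosen after its values were seen. H3K4me3 covered 83.9% of it, against a median of 14.7%, it held 5 H3K27ac peaks, and its signal was 18.5 times the input, at rank 20. Its assigned target, PRSS12, lies 1921 kb away. The 4 super-enhancers of JARID2, a partner of Polycomb complexes, add up to 232 kb, and the pair of SATB1 to 354 kb. Chromosome 21, with RUNX1, ERG and SAMSN1, had 10.5 super-enhancers per 1000 H3K27ac peaks, above the 9.49 of chromosome 8. At GATA1 the nearest peaks lay inside the gene, with folds of 6.32 for H3K27ac and 6.16 for H3K4me3, and at UBB they lay 3788 and 3731 bp away. The region names carry a number of joined peaks with a median of 11, whereas the regions overlapped a median of 19 peaks of the deposited list, and 515 regions overlapped more than their name states.

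Super-enhancers were more frequent on the segments of chromosomes 8 and 15 with raised background, with 1.74 times (1.28 to 2.33) as many per H3K27ac peak and 2.53 times (1.85 to 3.39) as many per gene as elsewhere. These intervals leave out the spread between chromosomes. Per 100 genes the segments had 6.36, against 1.43 to 5.86 on the 21 other chromosomes. Per 1000 H3K27ac peaks, chromosomes ran from 3.29 on chromosome 4 to 10.5 on chromosome 21, whose background was not raised. Dividing the difference of H3K27ac and input by the background ratio left a rate ratio of 0.697 (0.422 to 1.09) per peak and 1.01 (0.613 to 1.58) per gene, and MYC then ranked 4 in place of 1. Copy number carried into a ranking by difference is a candidate explanation that this test could not decide, because an excess with no effect of copy number would come out at 0.521 per peak after the same division, which leaves 144 of 482 regions elsewhere (29.9%) and 20 of 50 on the segments (40%). More peaks called at higher copy number, with 1.45 times (1.41 to 1.49) as many H3K27ac peaks per gene, may add to the excess per gene but not through their number to that per peak, though gene density stays open and the reading of the 1.45 was made stricter after it was seen. No biological explanation was tested, since the design has no group that bears on it.

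H3K4me3 summits levelled off, with an upper quartile of 221 fragments and a highest value of 345. At gene ends on the raised segments the 90th percentile was 330 fragments against 287 elsewhere, a ratio of 1.15 (1.14 to 1.16), after 1.62 at the lower quartile and 1.27 at the median. The H3K27ac ratio also fell towards the top, from 1.67 (1.49 to 1.8) at the median to 1.40 (1.36 to 1.43) at the 90th percentile and 279 against 223 fragments at the 99th. The ratio of 1.15 argues against nucleosomes that carry the mark in full as the only cause, which predicted a ratio above 1.6. It cannot tell whether they do carry it in full, since a cap would hold the ratio down either way. No other biological explanation was tested. A cap on the fragments counted per position may be the cause and would understate H3K4me3 folds at strong promoters on those segments, where the median fold was 0.776 times that elsewhere.

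Of 460 protein-coding super-enhancer targets 36 had no H3K4me3 at either end, among them MEF2C, RUNX3 and RARA. An H3K4me3 peak lay inside the gene in 83.3% of them (30 of 36, 68.1 to 92.1), against 20.2% of other genes without the mark at an end, so an internal promoter or a shorter isoform may be the reason, as at RUNX3 (fold 78.8) and MEF2C (fold 58.1). Super-enhancers themselves hold H3K4me3 and often overlap their target, which raises this share. For 75% (27 of 36, 58.9 to 86.2) the strongest peak inside reached the median fold of the list (10.2). That value cannot remove the concern, because the strongest of several peaks was set against single peaks. No such share was taken for other genes, and gene length was not matched. Targets chosen by position without a marked promoter account for at most part of the pattern, since 16.7% (6 of 36, 7.87 to 31.9) had no H3K4me3 in or near the gene, namely VSIG4, LCTL, RAB40AL, ITLN1, SLC15A2 and SLC23A1. The strand of the genes was not used, so which end holds the promoter stays open.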
